A study of Mus musculus with 3 samples.

How the data were processed

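The arrays measured RNA of PMN-MDSCs, sorted on CD11b and Ly6G, from tumor tissue, tumor-bearing spleen and wild-type spleen, 1 array each. Per the file headers, the signals are intensity values of a 1-colour (Cy3) scan, extracted with Agilent Feature Extraction 11.0.1.1 (the tool is also named in the submitters' processing notes), background-subtracted and detrended within each array but not scaled between arrays. The headers place all 3 arrays in 1 scan, with the same grid and extraction protocol, and give the mouse build of the grid as mm9. They record a multiplicative detrending on the tumor and wild-type arrays only. The scan thus gives no batch that separates the groups, but each group is a single array. The deposited value table of the series holds log2 values of the same arrays, and how the authors scaled it is not given in the sources used here. Its columns had Pearson r of 0.999, 0.999 and 0.999 with the log2 processed signals across probes, equal medians of 6.40 and equal maxima of 18.9, as quantile normalization leaves them, and 96 of the probes had no row in the table used here.

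From these files the processed signal of each spot was put on the log2 scale. Control spots and 147 spots with outlier flags were left out, repeated spots of a probe were averaged, and each array's 75th percentile over 60915 probes was subtracted. Those percentiles were 524, 509 and 698 signal units for tumor, tumor-bearing spleen and wild-type spleen. No spot was saturated. Negative probes (15, in 300 spots per array) served as a background check. A probe was compared when most of its spots were well above background on both arrays. A probe well above background on 1 of the 2 arrays was counted apart, with the bright array's value set against the higher of the lowest signal well above background on the dim array and the dim probe's own value, which gives a bound. The scanner's flag of well above background also marked 7.33%, 5.00% and 6.00% of the negative spots.

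The spot-to-spot error was taken from probes with at least 8 usable spots on an array, at least 90% of them well above background. It was an SD of 0.05 log2 units for probes 4 or more above the 75th percentile, 0.14 from 0 to 4 above it and 0.32 to 0.37 down to 4 below it. From 4 to 5 below it the SD was 0.31, from 5 pairs of probe and array, and the same value was used further down, where no pair was left. The rule left out noisy dim repeats such as ETG05_36762 on the tumor-bearing spleen array (SD 0.97). Counts from spot error alone may thus be too low for dim probes. How many probes this error alone would put past 2-fold was found from 20 draws. The error holds no variation between mice, dissections or hybridisations. The steps were tested on simulated arrays built from the wild-type array, for the tumor comparison with 46765 probes: of 100 probes changed 4-fold 98.0% were past the 2-fold limit in the right direction, of 100 changed exactly 2-fold 47.0% were, and of the unchanged ones 2.64% were past it.

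Gene names came from the RefSeq accessions that the files give for 15 reference probes, all of which matched a symbol in a RefSeq table of assembly GRCm38.p6 with versions left off. The table's assembly is not that of the grid, so no coordinates are given. The plan, fixed before the data were examined, was to count protein-coding genes and lncRNA transcripts, to name per comparison the 10 genes and 5 lncRNAs with the largest change in each direction, up to 4 members of each gene list, the largest bounds, and AK036396 and Fcnb. Since the files used here pair few probes with names, the counts are of all probes, of lincRNA-named probes and of the named reference genes, all 15 reference genes are named, and 2 lincRNA-named probes per direction are given for the tumor comparison. Of the 32 gene lists the housekeeping list alone had more than 1 member measured by a reference probe. The Pgk1 and Gapdh end probes were chosen as an RNA quality measure after the files were read.

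With 1 array per group nothing was tested and no p-value was computed. Lists were set beside 10000 random sets of other probes matched by 10 level classes of the mean over the 3 arrays. For lincRNA-named probes, these other probes had the array maker's identifier and did not include those of the prefix ASMM10UP. Alternatives were quantile normalization, scaling to the median of probes detected on all 3 arrays, the authors' value table, detection required on all 3 arrays or on none, and size limits of 1.5-fold and 4-fold. Added after the files were read were normexp background correction (offset 50) on the median spot and background signals, in place of mean spot signals, which were not used here, and background-subtracted signals without the multiplicative detrending. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, R 4.3.3 with limma 3.58.1, and matplotlib 3.10.9 for plots.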

Results

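Total RNA from polymorphonuclear myeloid-derived suppressor cells (PMN-MDSCs), neutrophil-lineage cells that restrain T cells in tumor-bearing hosts, was hybridised in 1 colour (Cy3) to an Arraystar mouse lncRNA array, which carries probes for long noncoding and coding transcripts. The cells came from male C57BL/6 mice of 6 to 8 weeks and were enriched with an MDSC kit and sorted for CD11b and Ly6G. The Ly6G antibody clone in the labels is usually sold as anti-Gr-1, which also binds Ly6C, and no named probe here marks a cell type, so the purity of the cells was not checked. The 3 groups were PMN-MDSCs of tumor tissue, of the spleen of tumor-bearing mice and of the spleen of wild-type mice, with 1 array per group. The name PMN-MDSCs is that of the labels, also for the wild-type mice, and whether the cells restrain T cells was not measured here. There were no replicates, so no difference below has a test or a replicate check, and a 2-fold difference is a descriptive size limit. The number of arrays limits the precision. Each array gave signals for 60915 probes, of which 46332 (76.1%) lay well above background with tumor cells, 44870 (73.7%) with cells from tumor-bearing spleen and 46765 (76.8%) with cells from wild-type spleen. Of 300 spots of negative probes, 22, 15 and 18 did so, respectively.

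Only 15 probes, all for reference genes, carried a RefSeq accession, and each was repeated in 20 spots. Another 1836 probes were named after lincRNA (long intergenic noncoding RNA) loci, 1104 of them with the prefix humanlincRNA, and 59064 bore the array maker's identifier alone. AK036396 and Fcnb, the lncRNA and the ficolin B gene of the series title, were not analysed here, because the files and the reference table used here do not pair them with a probe. For the same reason 29 of 32 gene lists fixed beforehand, on granule proteins, suppressive mediators, cytokines, interferon response, cell cycle and other cell types among others, had no measured member. By these reference probes the housekeeping list had 9 of its 18 genes measured, the hypoxia and glycolysis list had Gapdh alone and the antigen presentation list had B2m alone. Pgk1, a member of the first and second of these lists, was read only by control probes at its ends and was not counted in them. Levels below are log2 signals minus the 75th percentile of their array, and the error given with a log2 difference is the SD between repeated spots, combined over the 2 arrays, which is technical.

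The first comparison asked which transcripts differ between PMN-MDSCs of the tumor and PMN-MDSCs of wild-type spleen, the pair that the series design describes. Hsp90ab1 (NM_008302.3), a cytosolic chaperone, read 4.84-fold lower in tumor cells, a log2 difference of -2.27 ± 0.06 (SD, 1 array per group). Rpl13a (NM_009438.4), a protein of the large ribosomal subunit, read 4.68-fold lower at -2.23 ± 0.08. Gusb, the lysosomal beta-glucuronidase, and Nono, an RNA-binding protein of paraspeckles, differed by -1.25 ± 0.07 and -1.21 ± 0.08, but by only -0.86 and -0.82 after quantile normalization. G6pd2 (NM_019468.2) read 3.87-fold higher in tumor cells, at 1.95 ± 0.09. Its transcript is nearly identical to that of G6pdx, which encodes glucose-6-phosphate dehydrogenase, so its probe may read both. Ldhal6b, a lactate dehydrogenase A-like gene, differed by 1.22 ± 0.23 at a low signal of 137 units against 78.3, and by 0.86 under another background correction.

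The remaining 9 reference genes lay within 2-fold between tumor and wild-type spleen. Gk, the glycerol kinase, differed by 0.69 ± 0.12, the transferrin receptor gene Tfrc by -0.51 ± 0.07, the purine salvage gene Hprt by -0.43 ± 0.08 and Tbp by -0.41 ± 0.08. Tuba1b, an alpha-tubulin gene, differed by -0.37 ± 0.10, Gapdh by -0.28 ± 0.09, Ppia by -0.15 ± 0.08 and Actb by 0.28 ± 0.07. B2m, the light chain of MHC class I, differed by 0.06 ± 0.08, and its sign turned to -0.08 with the median of detected probes as the scale. Of the 9 measured housekeeping genes, 2 were at least 2-fold lower, Rpl13a and Gusb, and 0 were higher, with a list median of -0.41. That median lay at percentile 38.1 of 10000 random lists matched on level, whose medians ran from -1.16 to 0.77 between percentiles 2.5 and 97.5. After quantile normalization the middle gene of the list was Ppia, at -0.14.

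**Figure D1:**
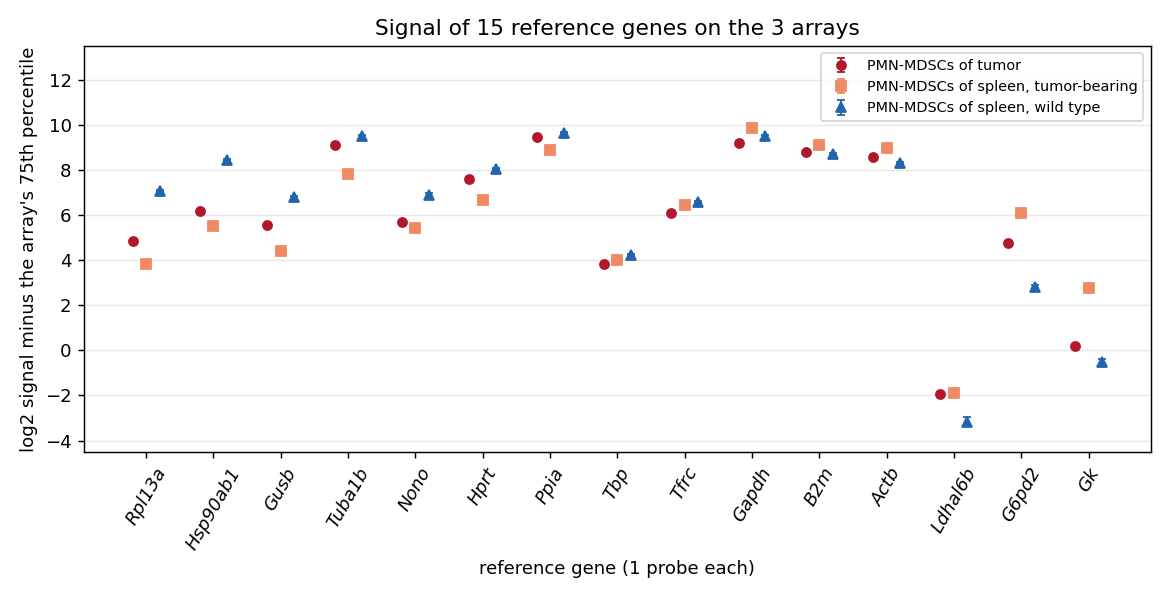
Log2 signal minus the array's 75th percentile (y axis) of the 15 reference genes (x axis), 1 probe per gene, on the arrays of tumor, tumor-bearing spleen and wild-type spleen PMN-MDSCs, to be compared within a gene. Points are means and bars the SD over 15 to 20 spots of 1 array, and Rpl13a, Hsp90ab1, Gusb and Nono stand lower on both arrays of tumor-bearing mice than in wild type, while G6pd2 stands at 4.77 and 6.09 there and at 2.82 in wild type.

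Over all probes, 43421 were well above background on both arrays, of which 8498 (19.6%) were at least 2-fold higher in tumor cells and 7933 (18.3%) at least 2-fold lower. The larger side depended on the scaling: with the median of detected probes as the scale, 7389 were higher and 9114 lower. Draws from the spot-to-spot error alone put 1119.6 past the limit. A further 2906 probes were well above background only on the tumor array, 1485 of them at least 2-fold higher by a bound against the dimmest detected signal, and 3337 only on the wild-type array, 1537 of them at least 2-fold lower in tumor cells.

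Probes named after lincRNA loci differed less often. Of 781 measured on both arrays, 74 were higher and 47 lower in tumor cells (62 and 70 with the median of detected probes as the scale), which is 15.5% past the limit. Among 42234 probes with the array maker's identifier, without those of the prefix ASMM10UP described below, 38.4% were past it. Among random sets of these matched on level 32.6% were (29.4% to 35.7% between percentiles 2.5 and 97.5 of 10000 sets). The lincRNA-named probes furthest up were mouselincRNA1099-_P1, 27.8-fold higher at a log2 difference of 4.80, and humanlincRNA2208-_P1, 22.4-fold higher at 4.48. Both folds rest on low wild-type signals, of 35.3 and 43.3 units, and are uncertain in size. Those furthest down were MM9LINCRNAEXON10569-_P1, at -4.97, and humanlincRNA0324-_P1, at -4.52. Each of these 4 had 1 spot per array, and the SD between repeated spots at their mean level over the 3 arrays was 0.32 for the former pair and 0.14 for the latter.

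The second comparison set PMN-MDSCs of the spleen of tumor-bearing mice against those of wild-type spleen, the same organ in both groups. Gk (NM_008194.3) read 9.81-fold higher in tumor-bearing spleen, at 3.29 ± 0.14, and G6pd2, with the limit on its probe given above, 9.60-fold higher at 3.26 ± 0.08. Ldhal6b differed by 1.25 ± 0.26, and by 0.87 under the other background correction. Rpl13a read 9.61-fold lower, at -3.27 ± 0.07, Hsp90ab1 7.59-fold lower at -2.92 ± 0.11 and Gusb 5.23-fold lower at -2.39 ± 0.07. Tuba1b followed at -1.65 ± 0.08, Nono at -1.50 ± 0.07 and Hprt at -1.38 ± 0.08. These 6 stayed at least 2-fold lower under each scaling and background correction tried.

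Within 2-fold lay Ppia at -0.73 ± 0.06, Actb at 0.67 ± 0.05, B2m at 0.38 ± 0.06 and Gapdh at 0.37 ± 0.08. Tbp differed by -0.24 ± 0.08 and Tfrc by -0.14 ± 0.08, and after quantile normalization both signs turned, to 0.03 and 0.21. Of the 9 housekeeping genes, 3 were at least 2-fold lower, Rpl13a, Gusb and Hprt, and 0 were higher. The list median was -0.24, at percentile 46.0 of matched random lists. It was the value of Tbp, and after quantile normalization Tbp was again the middle gene, at 0.03, so the sign of the median depended on the scaling.

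Control probes at both ends of 2 transcripts, which bear on RNA length, did not move alike. The 5′ probe of Pgk1, a glycolytic kinase, read lower than in wild-type spleen by a log2 difference of -1.93 ± 0.10 in tumor-bearing spleen and -1.98 ± 0.08 in tumor, while its 3′ probe differed by -0.56 ± 0.06 and -0.85 ± 0.04. For Gapdh the 5′ probe differed by 0.13 ± 0.08 and -0.60 ± 0.07, and the 3′ probe by 0.29 ± 0.06 and -0.55 ± 0.06.

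**Figure D2:**
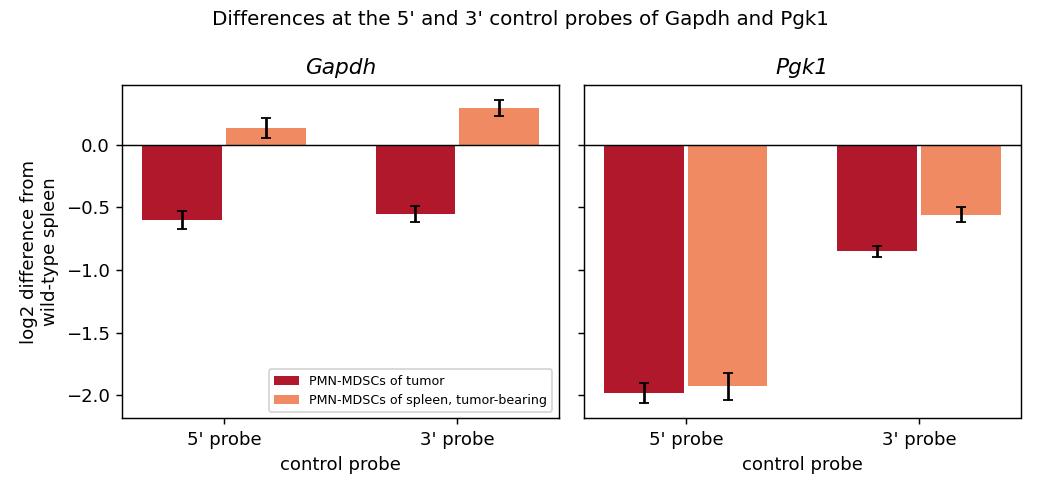
Log2 difference from wild-type spleen (y axis) at the 5′ and 3′ control probes (x axis) of Gapdh and Pgk1, for PMN-MDSCs of tumor and of tumor-bearing spleen. Bars are differences of means over up to 10 spots and error bars the combined SD between spots, and Pgk1 differs by -1.98 and -1.93 at its 5′ probe and by less at its 3′ probe.

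Of 42323 probes measured in both spleens, 11600 (27.4%) were at least 2-fold higher in tumor-bearing mice and 9260 (21.9%) at least 2-fold lower, against 1084.5 from spot error alone. With the median of detected probes as the scale the larger side turned, to 9725 higher and 10208 lower. A further 2541 were well above background only in tumor-bearing spleen, 1419 of them at least 2-fold higher by a bound, and 4438 only in wild-type spleen, 1944 of them at least 2-fold lower. The median difference over the probes measured in both was 0.29. Probes named after lincRNA loci leaned to one side: of 766 measured, 257 (33.6%) were higher in tumor-bearing spleen and 38 (4.96%) lower, with a median difference of 0.67. Random sets of other probes matched on level had 23.2% higher (20.2% to 26.1%) and 16.7% lower (14.2% to 19.3%). In the brighter part of the lincRNA-named probes, above their median level, 171 of 383 were higher and 20 lower. Under normexp background correction 143 lincRNA-named probes were higher and 10 lower, with a median of 0.50.

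The last comparison asked how PMN-MDSCs of the tumor differ from those of the spleen of tumor-bearing mice. Gk read 6.07-fold lower in the tumor, at -2.60 ± 0.08, and G6pd2 2.48-fold lower at -1.31 ± 0.09. Tuba1b read 2.43-fold higher in the tumor at 1.28 ± 0.07, Gusb 2.19-fold higher at 1.13 ± 0.04 and Rpl13a 2.05-fold higher at 1.04 ± 0.08. The remaining 10 genes lay within 2-fold, from -0.64 ± 0.06 for Gapdh to 0.94 ± 0.09 for Hprt, and Ldhal6b, at -0.03 ± 0.18, had no fixed sign (0.05 in the authors' value table). Of the 9 housekeeping genes, 2 were at least 2-fold higher, Rpl13a and Gusb, and 0 lower. The list median was -0.17, at percentile 21.6 of matched random lists.

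Of 42843 probes measured on both arrays of tumor-bearing mice, 6069 (14.2%) were at least 2-fold higher in the tumor and 6316 (14.7%) at least 2-fold lower, against 1111.0 from spot error alone. With no filter on dim probes the larger side turned, to 9919 higher and 9166 lower. Only with tumor cells were 3485 well above background, 1018 of them at least 2-fold higher by a bound, and only with tumor-bearing spleen 2019, 700 of them at least 2-fold lower. Of 786 lincRNA-named probes, 31 (3.94%) were higher in the tumor and 213 (27.1%) lower, with a median difference of -0.50. Under normexp background correction 3 were higher and 114 lower, with a median of -0.25, and with no filter on dim probes the median was -0.22. Matched sets of other probes had 12.6% higher (10.3% to 14.9%) and 12.8% lower (10.7% to 15.3%).

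**Figure D3:**
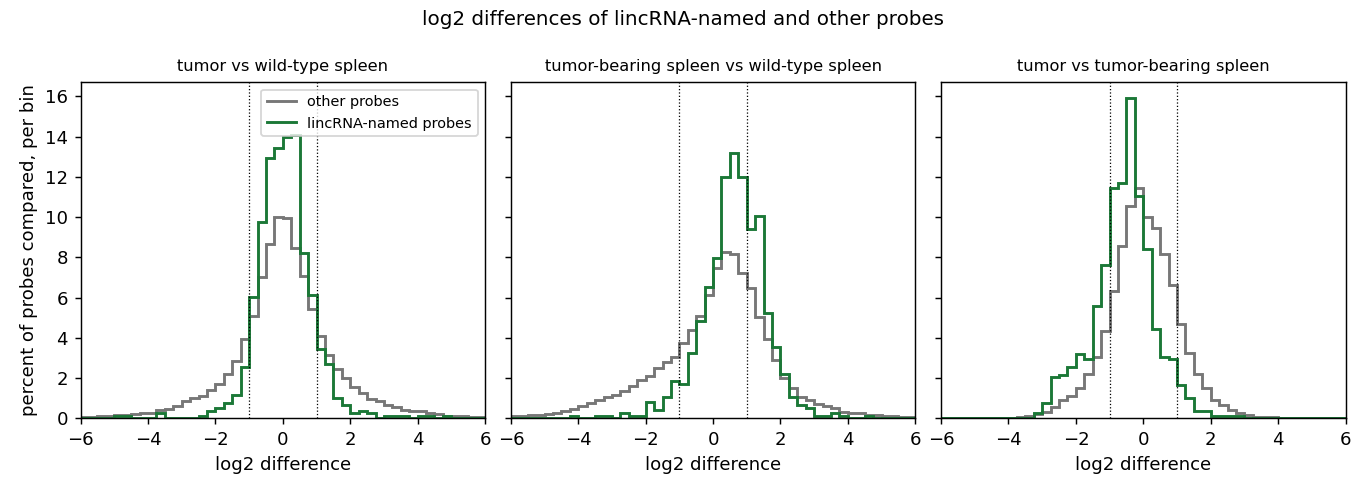
Histograms of log2 differences (x axis) as percent of the probes compared per bin (y axis), for probes named after lincRNA loci and for other probes with the array maker's identifier (those of the prefix ASMM10UP left out), in the 3 comparisons. Dotted lines mark 2-fold, and the lincRNA-named probes sit to the right between the spleens, with a median of 0.67, and to the left between tumor and tumor-bearing spleen, with a median of -0.50.

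Many differences from wild-type spleen were common to both arrays of tumor-bearing mice. Among 41251 probes well above background on all 3 arrays, 5938 were at least 2-fold higher in both comparisons and 5971 at least 2-fold lower in both, while independent lists of these sizes would share 2298.3 and 1616.1. The shared probes were 71.8% of the 8275 higher and 81.5% of the 7322 lower in the tumor, but 51.8% of the 11457 higher and 65.6% of the 9105 lower in tumor-bearing spleen. Only 85 probes were higher in the tumor and lower in tumor-bearing spleen, and 229 the reverse. Both comparisons use the same wild-type array, and spot error alone, drawn with that array in common, gave 94.8 and 92.8 shared probes. Part or all of the excess may come from the shared array, since its animal-to-animal error is not known and the draws hold none. Across probes, which are not independent replicates, the 2 sets of differences had a Pearson r of 0.819, beside 0.502 in the draws, and a covariance of 2.34, beside 0.0799 in the draws. The wild-type array stood apart from 2 mutually similar arrays at 8855 probes (21.5%), the tumor-bearing spleen array at 5015 (12.2%) and the tumor array at 1756 (4.26%). For the lincRNA-named probes this order differed, with 150 of 714 (21.0%) apart on the tumor-bearing spleen array, 139 of them higher, 58 on the wild-type array and 18 on the tumor array.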

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

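All tests in this part were chosen after the result was seen, except the match on level for how often lincRNA-named probes differ 2-fold between tumor and wild-type spleen.

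Control probes that belong to no comparison differed from the wild-type array in both directions. Probe ETG09_48764 was well above background in 11 of 11 spots on the tumor array and in 0 of 12 on the wild-type array, at least 1.78 log2 units higher (at least 3.44-fold, or 1.37 log2 units before scaling). On the tumor-bearing spleen array, ERCC-00012_90 read 1.13 higher than on the wild-type array (0.68 before scaling), ERCC-00062_278 read 1.39 higher (0.94 before scaling), ETG05_66023 read 1.104 higher (0.65 before scaling) and GE_BrightCorner read 1.40 higher (0.94 before scaling). In the other direction, (+)E1A_r60_a107 was well above background in 35 of 35 spots on the wild-type array and differed by -3.26 on the tumor array and by -3.59 or below on the tumor-bearing spleen array, where 2 of 34 spots were. The other control probes at least 2-fold lower than on the wild-type array were end probes of Pgk1 and Gapdh, most of them 5′: on the tumor and tumor-bearing spleen arrays Human-PGK1_5 differed by -1.94 and -1.99, Rat-PGK1_5 by -1.95 and -1.94 and Rat-PGK1_3 by -2.03 and -1.49, besides the mouse 5′ probe of Pgk1, and on the tumor array alone Human-GAPDH_5 differed by -1.04 and Rat-GAPDH_5 by -1.20.

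The wild-type spleen array lay farther from both other arrays than those lay from each other: the SD of log2 differences was 1.61 and 1.80 against wild type and 1.04 between the arrays of tumor-bearing mice. A constant scaling factor cannot change such an SD, so it was not at issue. A scaling difference that varies with signal is argued against, because after quantile normalization the smaller distance from wild type was still 1.52 times the distance between the other arrays. A gradient over the slide is argued against as well, since at most 1.62% of the variance of differences from the wild-type array lay between blocks of 16 rows and 16 columns, and so are spots of uneven local background, of which the wild-type array had 1256 where the others had 56 and 49: without the 2677 probes with an outlier in local background on any array, the ratio was 1.54. A difference in RNA integrity cannot be told apart from the groups: the change of the 5′ probe of Pgk1 from wild-type spleen minus that of its 3′ probe was -1.13 ± 0.09 in tumor and -1.37 ± 0.12 in tumor-bearing spleen, while for Gapdh the figures were -0.05 ± 0.10 and -0.16 ± 0.10. In the same order of arrays, the human probes gave -0.97 ± 0.12 and -1.58 ± 0.10 for Pgk1 and -0.32 ± 0.09 and -0.06 ± 0.10 for Gapdh, and the rat probes 0.09 ± 1.20 and -0.45 ± 1.01 for Pgk1 and -0.22 ± 0.14 and -0.48 ± 0.14 for Gapdh, so with 2 transcripts that differ and 1 array per group no value decides, and tumor bearing itself stays open and untested.

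LincRNA-named probes differed 2-fold between tumor and wild-type spleen less often than other probes. Lower signal of these probes is argued against as the whole cause, because their share lay -17.1 percentage points from that of other probes matched on level, below the range of the random sets. A biological difference between these transcript classes stays a hypothesis, and other properties of the probes, such as how often the named locus is transcribed in these cells at all, stay open. The lower share was not seen in the other comparisons. The SD of log2 differences was still smaller for lincRNA-named probes than for all probes in each comparison. It was 0.85 against 1.61 between tumor and wild-type spleen and 0.96 against 1.80 between the spleens. Between tumor and tumor-bearing spleen it was 0.90 against 1.04. These SDs were not matched on level. The share past 2-fold also rises with a one-sided shift, so it does not tell how variable these probes are. Between the spleens 38.5% of them were past 2-fold, beside 39.9% in matched sets (36.6% to 43.1%). Between tumor and tumor-bearing spleen 31.0% were, beside 25.4% (22.5% to 28.4%).

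The same probes read higher on the array of tumor-bearing spleen than on either other array. Lower signal is argued against: 10.4 percentage points more of them were higher than in wild-type spleen compared with other probes matched on level, and against the tumor 27.1% read lower in the tumor where percentile 97.5 of the matched sets was 15.3%. These matched sets left out the ASMM10UP probes described below, which shifted alike, with medians of 0.69 between the spleens and -0.30 for tumor minus tumor-bearing spleen. The shift was thus not particular to lincRNA-named probes. The choice among the scalings used is argued against too, since the median difference of lincRNA-named probes was 0.49 or more against either array under each of 4 scalings. Of these, quantile normalization and the authors' value table gave nearly the same values. None of the scalings run here was set on control probes, so an offset common to most probes of that array was not tested and stays open. Other probes had medians of 0.12 to 0.28 between the spleens and of -0.04 to -0.01 for tumor minus tumor-bearing spleen under these scalings. The median of lincRNA-named probes shrank under normexp background correction, to 0.50 against wild-type spleen (other probes 0.30) and -0.25 for tumor minus tumor-bearing spleen (other probes -0.03), and with no filter on dim probes, to 0.37 (0.26) and -0.22 (-0.07). The size of its excess over the 0.28 and -0.03 of other probes thus depends on the processing. Normexp changes several steps together, so the cause was not tested. In the main setting the brighter part of these probes had medians of 0.89 and -0.70, and the dimmer part 0.52 and -0.38. Since the pattern lies on 1 array, a difference in RNA quality, labelling or hybridisation of that array stays open. On it the 4 control probes above read 1.104 to 1.40 higher than on the wild-type array (0.65 to 0.94 before scaling), while (+)E1A_r60_a107 and end probes of Pgk1 read at least 2-fold lower. A higher level of these transcripts in splenic PMN-MDSCs of tumor-bearing mice stays open too, only as a hypothesis. Probe names and strands limit that reading. Of probes named humanlincRNA, a prefix not explained in the sources used here, 148 of 445 were higher than in wild-type spleen and 19 lower, beside 87 of 276 and 15 for mouselincRNA. Of 154 loci measured on both strands, 46 were higher on the plus and 51 on the minus strand.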

How the results depend on the processing

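The alternatives on median signals and on detrending were chosen after seeing the data, and the others before. Of the counts of probes or genes recomputed under 9 alternatives, 131 stayed within 1.5 times the reported count and 49 did not. No 2-fold difference of a named gene changed sign. Scaling to the median of probes detected on all 3 arrays moved the median difference over all probes from 0.02 to -0.13 for tumor against wild-type spleen and from 0.29 to 0.13 between the spleens. It also turned which side had more probes, from 51.7% to 44.8% of 2-fold calls higher for tumor against wild-type spleen and from 55.6% to 48.8% between the spleens, and among lincRNA-named probes of the former from 74 higher and 47 lower to 62 and 70. Normexp moved the median difference of the former to 0.13. The counts below name higher then lower. Under the 1.5-fold limit the counts were, for tumor against wild-type spleen, 12817 and 12103 probes, with 159 and 144 lincRNA-named, for tumor-bearing against wild-type spleen 415 and 69 lincRNA-named, and for tumor against tumor-bearing spleen 11110 and 11419 probes, 70 and 353 lincRNA-named and 5 reference genes higher, with 9311 probes higher in both comparisons with wild type. Under the 4-fold limit they were, in the same order of comparisons, 3458 and 3379 probes, 13 and 8 lincRNA-named and 0 and 2 reference genes, then 3719 and 4906 probes, 41 and 7 lincRNA-named and 3 reference genes lower, then 1166 and 1478 probes, 4 and 61 lincRNA-named and 0 and 1 reference genes, with 2199 and 2638 probes shared. A changed limit moves such counts by construction. With no filter on dim probes, which adds probes near background, lincRNA-named probes numbered 241 and 177, 488 and 184, and 164 and 392. In that setting 9919 probes were higher and 9166 lower in tumor than in tumor-bearing spleen, so the larger side turned, from 49.0% to 52.0% of 2-fold calls higher. With normexp on median signals, which changes the spot summary, the background model and the offset together, so that no single cause was tested, they numbered 24 and 18, 143 and 10, and 3 and 114, while 3770 and 3984 probes differed between tumor and tumor-bearing spleen and 1 reference gene was higher in tumor than in wild-type spleen. Under quantile normalization and in the authors' value table only 2 of the 4 reference genes reported as lower were at least 2-fold lower in tumor than in wild-type spleen, and the cause was not tested. Among 4-fold calls between the spleens 43.1% were higher in tumor-bearing mice, against 55.6% of 2-fold calls. The 4 gene differences whose sign depended on the scaling were all within 2-fold. Not run were mean signals, the mean over a gene's probes, since each named gene had 1 reference probe, and keeping saturated spots, since there were none. Gapdh also had control probes at its ends, which were not averaged with it. Its tumor minus wild-type difference was -0.28 ± 0.09 at the reference probe, -0.60 ± 0.07 at the 5′ and -0.55 ± 0.06 at the 3′ probe. The SD between spots thus does not cover the difference between probes of a gene. No paired analysis was possible because each group is 1 array. Of the lincRNA-named probes 49.0%, 49.1% and 48.7% were well above background on the arrays of tumor, tumor-bearing spleen and wild-type spleen.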

Other observations

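All values in this part were chosen after the data were seen. A class of 923 probes whose array maker's identifier begins with ASMM10UP, a prefix whose meaning is not given in the sources used here, read higher more often than lower in tumor-bearing spleen, and was not set beside probes matched on level. Of 375 measured in both spleens 133 were at least 2-fold higher in tumor-bearing mice and 29 lower, with a median of 0.69, and of 401 measured in tumor and tumor-bearing spleen 34 were higher in the tumor and 76 lower, with a median of -0.30. Between tumor and wild-type spleen 76 of 391 were higher in the tumor and 24 lower, with a median of 0.14 that turned to -0.000853 with the median of detected probes as the scale. With no filter on dim probes the median between the spleens was 0.35 and that between tumor and tumor-bearing spleen -0.17, and under normexp the latter was -0.15.

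Most lincRNA loci on the array had a probe for each strand, 876 of 960. On the array of wild-type spleen both strands were well above background at 208 of these loci, 1 strand at 435 and neither at 233, while independent strands would give 206.6 loci with both. The counts for both strands on the other arrays were 212 with tumor cells, where independence would give 205.6, and 215 with tumor-bearing spleen, where it would give 207.6. Changes at the strands of a locus were at most weakly related: between the spleens, Pearson r across 154 loci was 0.01, and both strands were at least 2-fold higher in tumor-bearing mice at 19 loci, beside 15.2 for independent strands. Between tumor and tumor-bearing spleen r was 0.15 across 163 loci, and both strands were at least 2-fold lower in the tumor at 17 loci, beside 12.1 for independent strands. Between tumor and wild-type spleen r was 0.08 across 164 loci.

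Of the probes detected on all 3 arrays, the 10313 at or above percentile 75 of mean level were not closer between arrays than the full set. Their SD of log2 differences was 2.11 between the spleens and 1.76 between tumor and wild-type spleen, where that of all compared probes was 1.80 and 1.61. Past 2-fold lay 63.2% and 46.3% of them in these comparisons and 32.7% between tumor and tumor-bearing spleen.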
